A study of Mus musculus with 6 samples.

How the data were processed

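The series held 6 RNA sequencing libraries from mouse thalamus, 3 of immunopurified ribosome-bound RNA (IP) and 3 of Input. Groups and replicate numbers were taken from the sample titles, and lane numbers 3, 8 and 4 for replicates 1, 2 and 3 from the descriptions, so lane and replicate number cannot be told apart. Per the labels' protocols, thalamus was dissected and homogenised, and tagged polysomes were purified with anti-EGFP antibodies on magnetic beads. The labels give ribosomal-bound RNA as the molecule of the Input libraries too, and Input was taken as RNA of the whole tissue without a test of this. The library kit and its strand are not given in the sources used here.

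The authors deposited 1 table of whole-number read counts per gene for each library. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.0.0e and counted with HTSeq. The annotation, the HTSeq mode and the strand setting are not given in the sources used here. Each table held 32531 gene rows. Summary rows were kept out of library sizes and tests. On average they gave 7.8% of records with no feature in IP and 16.2% in Input, 1.8% and 9.3% ambiguous, and 40.8% and 25.8% alignments at more than 1 place. Counts of genes with near-identical copies, such as ribosomal protein and globin genes, are low or uncertain for this reason, and without a known strand setting reads of overlapping and antisense genes cannot be told apart. Of the feature names, 8381 were clone accessions, with 1.06% of gene reads in IP and 10.15% in Input on average. By current symbol 23155 names matched the annotation (GENCODE M21 and RefSeq, on GRCm38, the assembly of mm10), 768 by an older symbol, and 8608 did not. No 2 libraries of the same group agreed within sampling noise.

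From the counts, genes were filtered with filterByExpr by group, scaled with TMM factors and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test on group, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled, and SE values are those of the log2 fold change of IP minus Input. The design, the alternatives and 26 gene lists were set before the data were examined, and 25 lists had at least 3 tested members. None of the 13 names of the mitochondrially encoded list matched a row, so it was not tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance in 1 direction. Adjustment was over lists.

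The named genes were 16 set in advance, the 8 largest changes in each direction among called genes with a mean of at least 5 CPM and no overlap of the groups, and from each list up to 3 called members in its main direction and up to 1 in the other. Where a list had no called member, its most abundant members were named. Protein-coding genes with the largest falls under the same minimum of 5 CPM and no overlap were added after their values were seen, since the rule gave only clone accessions. Some genes that the rule names are not reported here.

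Same-numbered IP and Input libraries deviated together from their group means, with correlations across genes of 0.244, 0.104 and 0.127 for replicates 1, 2 and 3. All were over 0.1, so the numbers were taken to pair the libraries, and this was decided before calls were compared. The fit without the replicate block stayed the main one, as set in the design, since the labels state no paired test. Calls from it thus leave the pairing out. The pairing comes from the titles. Results with the replicate block stand beside those of the fit without it at least where a call changed or a count of calls moved by over 1.5 times.

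On simulated counts for 16496 genes of IP against Input, with 200 genes changed, of which 192 passed the filter, 0 of 65 genes changed by log2 0.5 were recovered, 4 of 66 at log2 1 and 38 of 61 at log2 2, with 2.3% false calls. In the data 25.2% of tested genes were called, a far larger share than was changed in the simulation. The adjustment is less strict when more genes change, so these recoveries are not the sensitivity of the real fit. Gene totals between 44081149 and 54421395 reads per library limited counting error mainly for genes near the floor, and counting intervals cover counting error only. Alternatives were RLE, library total and upper-quartile scaling, DESeq2 1.42.0, limma-voom, other filters on low counts, a fold threshold, the replicate block, leaving out each library or replicate number, and leaving out abundant noncoding RNA. Leaving out clone-accession features as well was added after seeing the data. Checks of length, GC content and permutations used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.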

Results

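Ribosome-bound RNA was profiled in the thalamus of untreated adult mice of the Slc17a6-EGFP/Rpl10a line JX883 by translating ribosome affinity purification (TRAP). In TRAP, a ribosomal protein fused to EGFP is expressed in a chosen cell type, and its ribosomes are pulled down from homogenised tissue with anti-EGFP antibodies. In this line the tag is Rpl10a, and the line is named for Slc17a6, the gene of the vesicular glutamate transporter VGLUT2. The series held 6 libraries, 3 of immunopurified RNA (IP) and 3 of thalamic input (Input), with replicate numbers 1 to 3 in each group. The IP libraries held 54421395, 52068141 and 53038700 gene reads in replicates 1, 2 and 3, and the Input libraries 47340321, 45101044 and 44081149. A count of 3 reads corresponded to between 0.055 and 0.068 CPM (counts scaled by library total). The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries, which may in part be technical. Y-linked reads, given below, show other animals in replicate 1 than in replicates 2 and 3. The comparison asked which transcripts were at higher or lower levels in IP than in Input. Input was taken as RNA of the whole tissue, which is an assumption, since the labels give ribosomal-bound RNA as its molecule too.

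Slc17a6, the gene that names the line, had 3627 ± 2479 CPM in IP and 1502 ± 1444 CPM in Input (SD, n = 3). Its level was higher in IP in 3 of 3 replicates, with log2 ratios of 1.04, 1.32 and 2.20, but the log2 fold change of 1.27 ± 0.68 (SE) did not pass the test (edgeR quasi-likelihood adjusted p = 0.206). With the replicate block the log2 fold change was 1.52 ± 0.19 and passed (edgeR adjusted p = 0.000246). Without Input replicate 1 it was 2.43 and passed (edgeR adjusted p = 0.0161), without both libraries of replicate 1 it was 1.70 and passed (edgeR adjusted p = 0.00893), and without IP replicate 1 it was 0.56 (edgeR adjusted p = 0.589). Slc17a6 lies on chromosome 7 from 51622006 to 51671119 (GRCm38, the assembly of mm10). Rpl10a, the ribosomal protein of the tag, had 5.27 ± 1.02 CPM in IP and 6.65 ± 1.47 CPM in Input (SD, n = 3), and its log2 fold change of -0.34 ± 0.37 did not pass (edgeR adjusted p = 0.550). Ribosomal protein genes have near-identical pseudogene copies, and alignments at more than 1 place were not counted to genes, so the Rpl10a level is uncertain. Across genes, log2(CPM + 1) values correlated with r between 0.983 and 0.990 within IP, between 0.960 and 0.986 within Input, and between 0.920 and 0.955 between the groups.

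**Figure D1:**
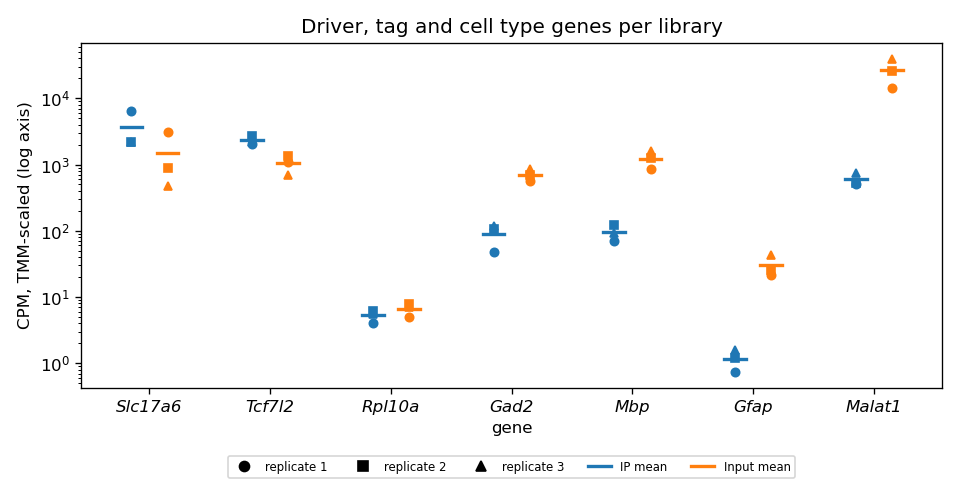
TMM-scaled CPM on a log axis for 7 genes in each library, with IP in blue, Input in orange, marker shapes for the replicates and bars for the group means. Slc17a6 overlapped between the groups, while Gad2, Mbp, Gfap and Malat1 lay lower in all 3 IP libraries.

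Of 16496 genes tested, 1583 were higher and 2566 lower in IP, and 12347 did not pass (edgeR quasi-likelihood test, adjusted p under 0.05). At a fold change of at least 2 in addition, 791 were higher and 2271 lower. Of the called genes, 100% after rounding had the same sign in 3 of 3 replicate pairs, which the call itself favours. The IP and Input values of 7399 genes (44.9%) did not overlap, against 10% by chance. Prph, an intermediate filament gene of peripheral and some central neurons, had the largest rise by the rule for named genes, at log2 3.49 ± 0.62 (SE), from 1.26 ± 0.85 CPM in Input to 14.2 ± 1.58 CPM in IP (SD, n = 3; edgeR adjusted p = 0.00541). Gpx3, a secreted glutathione peroxidase, rose by log2 2.57 ± 0.37 (edgeR adjusted p = 0.00219). Krt1 rose by log2 2.19 ± 0.30. Ptpn20, Ccdc109b and Spint2 had log2 fold changes of 2.73, 2.70 and 2.28. The calls of these last 3 genes ended when 1 library was left out, with edgeR adjusted p up to 0.0810, 0.0912 and 0.122. With the replicate block they passed (edgeR adjusted p = 0.00146, 0.00115 and 0.000765).

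The largest falls by the rule were all in features named by clone accessions, which the gene tables used here do not pair with gene names. Of these, X57780 fell by 7.22 on the log2 scale, from 4110 ± 417 CPM in Input to 27.5 ± 2.64 CPM in IP (SD, n = 3; edgeR adjusted p = 1.83e-06). Of 1395 tested features with such names, 24 were higher and 446 lower in IP. Among protein-coding genes, chosen after their values were seen, Heyl, Lcat, Fcer1g, Sdc4 and P2ry12 fell, with log2 fold changes of -6.02, -5.99, -5.90, -5.88 and -5.73. P2ry12 is a purinergic receptor of microglia, and Fcer1g a signalling subunit of Fc receptors in immune cells. With the replicate block the count of genes higher in IP was 2624 and that of lower genes 3163. The count of higher genes was 731, 810 or 808 without IP replicate 2, Input replicate 2 or IP replicate 3. Without IP replicate 2 the count of lower genes was 1634, and without both libraries of replicate 2 the counts were 83 higher and 651 lower.

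Of 23 tested oligodendrocyte genes, 23 fell (23 adjusted over the list alone), with a median log2 fold change of -4.29. Mbp, a myelin protein gene, fell from 1232 ± 359 CPM in Input to 95 ± 25.7 CPM in IP (SD, n = 3), a log2 fold change of -3.70 ± 0.30 (SE; edgeR adjusted p = 0.000169). Olig1 and Mal fell, with log2 fold changes of -4.29 and -3.78. Of 23 astrocyte genes, 20 fell (22 adjusted over the list alone), with a median of -3.69. Aqp4, the water channel of astrocyte endfeet, had a log2 fold change of -4.60 ± 0.34, Gfap of -4.69 ± 0.43, Ntsr2 of -4.39 and Gpr37l1 of -5.03. Of 22 microglial genes, 20 fell (21 adjusted over the list alone), with a median of -4.21, among them Cx3cr1, Csf1r and Laptm5 at -4.36, -3.75 and -4.61. Of 14 oligodendrocyte precursor genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone, 10 and 1 with the replicate block), with a median of -3.48, among them Gpr17, Vcan and Neu4 at -4.14, -5.01 and -4.87. The camera adjusted p was 6.17e-48 for oligodendrocytes, 8.64e-30 for astrocytes, 2.81e-14 for microglia and 1.25e-07 for precursors. With an estimated correlation the adjusted p was 0.0226 for oligodendrocytes, 0.0585 for astrocytes, 0.0501 for microglia and 0.0501 for precursors, so of all lists only that of oligodendrocytes held its call. With the replicate block as well, 0 lists held their call (adjusted p = 0.135 for oligodendrocytes with an estimated correlation). By fry with the replicate block, the adjusted p was 0.00891 for oligodendrocytes and microglia, 0.0111 for astrocytes and 0.0144 for precursors.

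Of 20 endothelial genes, 10 fell (12 adjusted over the list alone), with a median log2 fold change of -2.48 (camera adjusted p = 5.58e-05, and adjusted p = 0.0777 with an estimated correlation). Slco1a4 fell by 4.60 on the log2 scale, and Pltp had 4.10 ± 2.48 CPM in Input and 0.126 ± 0.0823 CPM in IP (SD, n = 3). Cldn5, a tight junction gene, had 1 IP read and 174 Input reads over the 3 libraries of each group, a ratio of 0.492% with a 95% counting interval from 0.0124% to 2.78%. Of 16 mural and fibroblast genes, 10 fell (13 adjusted over the list alone), with a median of -3.86 (camera adjusted p = 1.25e-07, and adjusted p = 0.0685 with an estimated correlation). Rgs5, a pericyte gene, had a log2 fold change of -5.05, Igf2 of -5.22 and Vtn of -4.14. Of 11 choroid plexus and ependymal genes, 5 fell (6 adjusted over the list alone, 8 with the replicate block), with a median of -3.21 (camera adjusted p = 0.00321, and adjusted p = 0.521 with an estimated correlation). Otx2, Ccdc153 and Foxj1 fell, with log2 fold changes of -2.82, -3.61 and -2.45. In Input replicate 3 this list stood a median of 5.60 times above the mean of the other Input libraries. All 4 tested erythrocyte genes fell (4 adjusted over the list alone), with a median of -4.23 (camera adjusted p = 0.00190, and adjusted p = 0.0799 with an estimated correlation). Hbb-bs, Hbb-b2 and Alas2 had log2 fold changes of -4.57, -5.20 and -3.22. The Alas2 call ended when 1 library was left out, with an edgeR adjusted p up to 0.0823. Globin genes have near-identical copies, so their counts are uncertain. Trem2 and Tie1 had no IP read, and with both at a floor of 3 reads over the group the microglial and endothelial medians were -4.21 and -2.48. At that floor both genes still lay below their list medians, so the medians could not move.

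**Figure D2:**
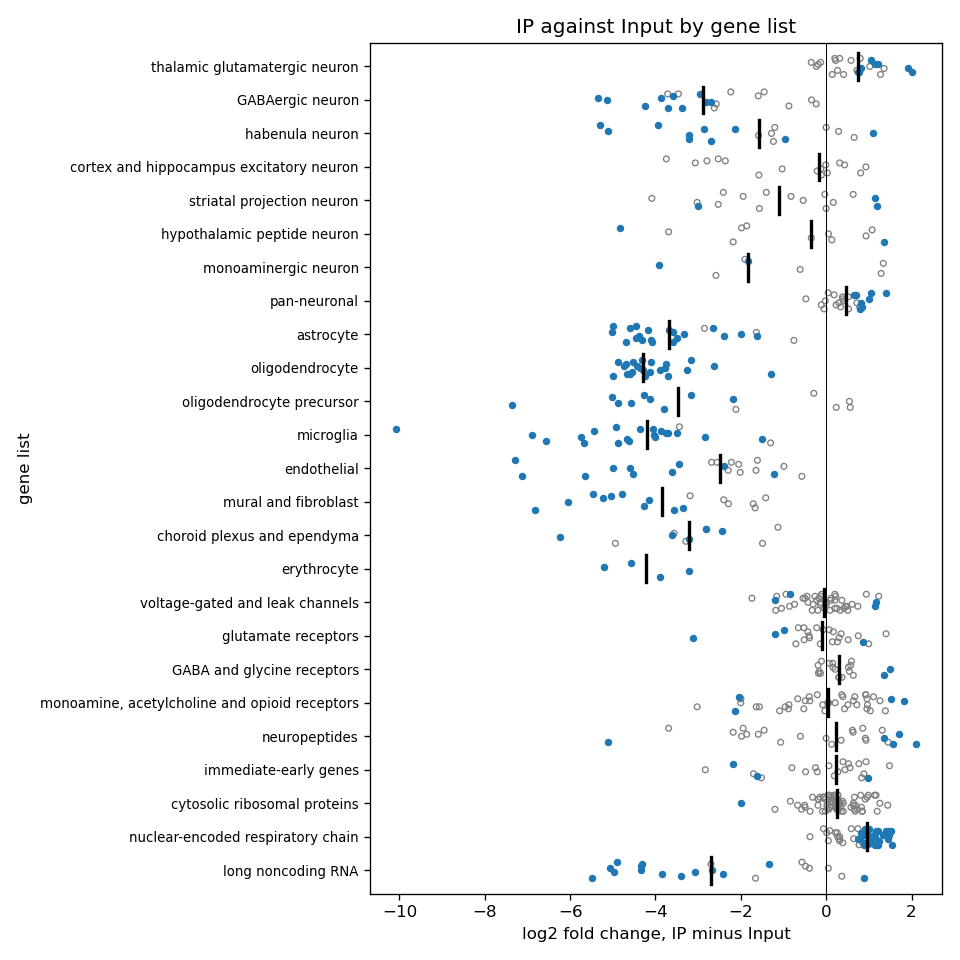
log2 fold change of IP minus Input for each tested member of 25 gene lists, with filled points for genes past the edgeR threshold, open points for the others and black bars for list medians. The 23 oligodendrocyte genes all lie below 0, with a median of -4.29, and the respiratory chain genes have a median of 0.95.

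Of 20 tested GABAergic genes, 10 fell (11 adjusted over the list alone, 16 with the replicate block), with a median log2 fold change of -2.88 (camera adjusted p = 1.47e-08, and adjusted p = 0.190 with an estimated correlation). In Input replicate 3 this list stood at a median of 1.94 times the mean of the other Input libraries, and 16 of its genes were highest there. Without that library its median was -2.69 (camera adjusted p = 3.29e-07). Gad1 and Gad2, the enzymes of GABA synthesis, fell, with log2 fold changes of -3.70 ± 0.46 and -2.95 ± 0.35 (SE; edgeR adjusted p = 0.00117 and 0.000907). Slc32a1, the vesicular GABA transporter, had a log2 fold change of -3.86 ± 0.30 and Six3 of -4.24. Of 24 thalamic glutamatergic genes, 8 rose (8 adjusted over the list alone, 13 with the replicate block) and 0 fell, with a median of 0.74 (camera adjusted p = 0.000103, and adjusted p = 0.453 with an estimated correlation and 0.0857 by fry). The counts were 9 and 0 by DESeq2, 8 and 0 by limma-voom, and 11 and 0 at an unadjusted edgeR p under 0.05. The thalamic list stood in Input replicate 3 at 0.52 times the mean of the other Input libraries, and without that library its median was 0.55 (camera adjusted p = 0.00395). Lhx2, a homeobox gene, rose by log2 2.02 ± 0.19, Calb2, calretinin, by 1.91 ± 0.31 and Tnnt1 by 1.21. Tcf7l2, a transcription factor of thalamic neurons on chromosome 19 from 55741820 to 55933654, rose from 1045 ± 333 CPM in Input to 2319 ± 361 CPM in IP (SD, n = 3), by log2 1.15 ± 0.25 (edgeR adjusted p = 0.0127). Without IP replicate 2 its edgeR adjusted p was 0.0501. Slc17a7, the vesicular glutamate transporter VGLUT1, had a log2 fold change of 0.58 ± 0.48 that did not pass (edgeR adjusted p = 0.417, and 0.0400 with the replicate block), and it was -0.08 without IP replicate 1.

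Of 24 pan-neuronal genes, 8 rose (10 adjusted over the list alone, 14 with the replicate block) and 0 fell (1 at an unadjusted edgeR p under 0.05 and 1 with the replicate block, 0 by DESeq2 and limma-voom), with a median log2 fold change of 0.46 (camera adjusted p = 0.000739, and adjusted p = 0.0685 with an estimated correlation). Random protein-coding lists matched on transcript length, GC content and expression had a median of 0.54, and 72.1% of 10000 such lists had a median as high as that of the pan-neuronal list. Stmn3, Uchl1 and Syn2 rose by log2 1.41, 1.05 and 0.99. Snap25, a synaptic vesicle fusion gene, had 17551 ± 4012 CPM in IP and 12207 ± 1425 CPM in Input (SD, n = 3), and its log2 fold change of 0.52 did not pass (edgeR adjusted p = 0.0848, and 0.00585 with the replicate block). Without IP replicate 1 the Snap25 value was 0.70 and passed (edgeR adjusted p = 0.0228), as it did without both libraries of replicate 1, at 0.63 (edgeR adjusted p = 0.0282). Of 17 habenula genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -1.58 (camera adjusted p = 0.00124, and adjusted p = 0.345 with an estimated correlation). Without 1 library or replicate number this median ranged from -2.67 to -1.02. Ano1, Nwd2 and Syt15 fell, with log2 fold changes of -5.30, -2.70 and -2.87. Gap43, a growth-cone gene, rose by log2 1.09, a call that ended without 1 library (edgeR adjusted p up to 0.0911).

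The lists of cortex and hippocampus, striatal, hypothalamic and monoaminergic markers did not pass with all 6 libraries. Of 16 cortex and hippocampus genes, 0 were called (0 adjusted over the list alone, 3 lower with the replicate block), with a camera adjusted p of 0.817. At an unadjusted edgeR p under 0.05, 1 was higher and 3 lower, and DESeq2 called 1 higher and 2 lower and limma-voom 0. Their median was -0.17, while camera gave the opposite sign. Camk2a and Mef2c, the most abundant of them, had log2 fold changes of -0.11 ± 0.25 and -0.12 ± 0.22. Of 16 striatal genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone, 2 and 4 with the replicate block), with a median of -1.11 (camera adjusted p = 0.810). Rasd2 and Syndig1l rose by log2 1.13 and 1.19, and Rgs9 fell by 3.02, and each call ended without 1 library (edgeR adjusted p up to 0.0524, 0.0697 and 0.0516). Rgs9 had 211 CPM in Input replicate 3 against 24.4 and 58.1 CPM in Input replicates 1 and 2, and its log2 fold change was -1.76 without Input replicate 3 (edgeR adjusted p = 0.0142). In Input replicate 3 the cortex and hippocampus list stood a median of 6.92 times, and the striatal list 3.98 times, above the mean of the other Input libraries. Without Input replicate 3 the cortex and hippocampus list had a median of 0.59 and passed (camera adjusted p = 0.0203), and the striatal median was 0.07 (camera adjusted p = 0.238). The cortex and hippocampus list passed in only 1 of 6 fits without 1 library. That fit kept IP replicate 3, where the list deviated from the IP mean by a median of log2 0.28, against -0.27 and -0.03 in IP replicates 1 and 2. Its call may thus come from removing 1 library of a pair. Of 11 hypothalamic genes, 1 rose and 1 fell (0 and 0 adjusted over the list alone, 1 and 3 with the replicate block), with a median of -0.35 (camera adjusted p = 0.813). These were Gal at log2 1.35 and Hdc, histidine decarboxylase, at -4.84, and each call ended without 1 library (edgeR adjusted p up to 0.133 and 0.108). Gal passed in 0 of 6 fits without 1 library, and not with library totals, upper-quartile factors or no filter (edgeR adjusted p = 0.0612, 0.0619 and 0.0560). Hdc passed in 2 of 6, and all 12 of its IP reads were in IP replicate 2, so no fold is given without that library. In Input replicate 3 the hypothalamic list stood at 0.21 times the mean of the other Input libraries. Of 7 monoaminergic genes, 2 fell and 0 rose (2 and 0 adjusted over the list alone, 3 and 1 with the replicate block), with a median of -1.84 (camera adjusted p = 0.552). These were Ddc at -1.84 and Slc6a3, the dopamine transporter, at -3.93, and each call ended without 1 library (edgeR adjusted p up to 0.0929 and 0.111). By limma-voom Slc6a3 had an adjusted p of 0.0828.

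Ion channel and receptor genes went both ways. Of 47 voltage-gated and leak channel genes, 2 rose and 2 fell (1 and 0 adjusted over the list alone, 7 and 8 with the replicate block), with a median log2 fold change of -0.04 and the opposite sign in camera (adjusted p = 0.701). Kcnc4 rose by log2 1.14, and Kcnt1 had -1.21. Of 24 glutamate receptor genes, 1 rose and 3 fell (0 and 1 adjusted over the list alone, 3 and 5 with the replicate block), with a median of -0.10 (camera adjusted p = 0.848). Grm3 fell by 3.13 ± 0.33 (SE), Gria3 had -1.20 and Gria2 -0.99, and Grm4 rose by log2 0.85. Of 19 GABA and glycine receptor genes, 2 rose (2 adjusted over the list alone, 6 with the replicate block), with a median of 0.29 (camera adjusted p = 0.0554, and 0.0129 with the replicate block). With an estimated correlation the adjusted p was 0.727, and 0.289 with the replicate block as well. This list stood in Input replicate 3 at 0.51 times the mean of the other Input libraries. Glra2, a glycine receptor subunit, rose by log2 1.49 ± 0.25 and Gabra5 by 1.35 ± 0.24. Of 40 monoamine, acetylcholine and opioid receptor genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone, 10 and 5 with the replicate block), with a median of 0.05, a mean of -0.10 and a camera adjusted p of 0.289. Hrh3, the histamine H3 receptor, rose by log2 1.52 ± 0.26 and Htr1d by 1.81, and Chrna3 fell by 2.14. The calls of Kcnc4, Kcnt1, Gria3, Gria2, Grm4 and Htr1d ended without 1 library, with edgeR adjusted p up to 0.0917, 0.103, 0.0854, 0.122, 0.158 and 0.0598. Each of them kept its call with the replicate block (edgeR adjusted p up to 0.00669). Without IP replicate 1 the Grm4 value was 0.56, and its edgeR adjusted p was 0.0580 with upper-quartile factors and 0.0574 with the stricter filter.

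Of 24 neuropeptide and secreted synaptic genes, 4 rose and 1 fell (2 and 1 adjusted over the list alone, 7 and 6 with the replicate block), with a median log2 fold change of 0.24, a mean of -0.31 and a camera adjusted p of 0.493. Cbln1, a secreted synapse organiser, rose by log2 1.72 ± 0.43 and Cck, cholecystokinin, by 1.57 ± 0.42 (SE), and Tac2 fell by 5.11. The calls of Cbln1 and Cck ended without 1 library (edgeR adjusted p up to 0.0592 and 0.0845), and limma-voom gave an adjusted p of 0.0923 for Tac2. With the replicate block Cbln1 and Cck passed (edgeR adjusted p = 3.3e-05 and 4.31e-05). Of 22 immediate-early genes, 1 rose and 2 fell (0 and 1 adjusted over the list alone, 5 and 2 with the replicate block), with a median of 0.23, a mean of -0.15 and a camera adjusted p of 0.339. Fos rose by log2 0.99 ± 0.30 (edgeR adjusted p = 0.0423), and Nr4a2 and Arc had log2 fold changes of -1.62 and -2.18. Fos did not pass with upper-quartile factors. Without 1 library the edgeR adjusted p of Fos reached 0.137 and that of Arc 0.142, and without Input replicate 3 the log2 fold change of Arc was -1.32. With the replicate block both passed (edgeR adjusted p = 0.0043 for Fos and 0.000115 for Arc). In Input replicate 3 this list stood at 1.81 times the mean of the other Input libraries. Without that library its median was 0.68 and the list passed (camera adjusted p = 0.0231), which it did in only 1 of 6 fits without 1 library. The list also passed without both libraries of replicate 3, at a median of 0.655 (camera adjusted p = 0.0495).

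Of 52 tested genes of the nuclear-encoded respiratory chain, 31 rose (35 adjusted over the list alone, 38 with the replicate block) and 0 fell, with a median log2 fold change of 0.95 (camera adjusted p = 2.94e-13, and adjusted p = 0.173 with an estimated correlation). The counts were 34 and 0 by DESeq2, 32 and 0 by limma-voom, and 38 and 0 at an unadjusted edgeR p under 0.05. Uqcrq, a subunit of complex III, rose from 62.1 ± 16.8 CPM in Input to 178 ± 2.42 CPM in IP (SD, n = 3). Cox5a, a subunit of cytochrome c oxidase, rose by log2 1.43 ± 0.20 and Atp5d, a subunit of ATP synthase, by 1.21 ± 0.16 (SE; edgeR adjusted p = 0.00206 and 0.00160). Random protein-coding lists matched in the same way had a median of 0.76, and 1.13% had a median as high as that of the respiratory chain list. Of 78 cytosolic ribosomal protein genes, 0 rose and 1 fell by edgeR (0 and 0 adjusted over the list alone, 7 and 0 with the replicate block, 7 and 1 at an unadjusted p under 0.05, 3 and 2 by DESeq2, 2 and 0 by limma-voom), with a median of 0.25 (camera adjusted p = 0.0209, and adjusted p = 0.784 with an estimated correlation). The member that fell was Rpl9 at -1.99 (edgeR adjusted p = 0.0496, and 0.0907 with the replicate block), and it passed in 0 of 6 fits without 1 library and not with RLE factors, library totals, limma-voom or no filter. The list call ended without Input replicate 1 (camera adjusted p = 0.334) and without IP replicate 2 (camera adjusted p = 0.0654).

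Of 21 tested long noncoding RNAs chosen in advance, 13 fell and 1 rose (15 and 1 adjusted over the list alone), with a median log2 fold change of -2.70 (camera adjusted p = 5.65e-16, and adjusted p = 0.0757 with an estimated correlation). Malat1, a nuclear RNA, fell from 26606 ± 12740 CPM in Input to 596 ± 131 CPM in IP (SD, n = 3), a log2 fold change of -5.48 ± 0.40 (SE) (edgeR adjusted p = 0.000121). Meg3, Rian and Miat fell, with log2 fold changes of -5.06, -3.08 and -4.89. Peg13 rose by log2 0.89 ± 0.17 (edgeR adjusted p = 0.00650). It is annotated as sense intronic, so it lies within another gene on the same strand. Strand cannot tell its reads from unspliced reads of that gene, so its count is uncertain. By annotated class, 10.9% of 14218 protein-coding genes were higher and 13.6% lower, against 1.7% higher and 16.7% lower of 234 lincRNA genes and 0.9% higher and 19.5% lower of 226 antisense genes.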

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

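The test of ribosomal RNA was chosen after its result had in part been seen. The tests of GC content, length and sex chromosomes were set before their results, but after the shared deviation of replicate 1 and the Y-linked levels had been seen. The share of alignments at more than 1 place, which no comparison above used, was higher in IP (40.8 ± 3.6%, SD, n = 3) than in Input (25.8 ± 1.9%), a difference of 15 percentage points with no overlap of the groups, and 3 libraries against 3 cannot give an exact p below 0.1.

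The real split of the libraries gave 4149 called genes, and the highest of the other splits gave 0 (edgeR quasi-likelihood test). The other splits gave up to 800 genes at an unadjusted p under 0.05, against 6300 in the real one, and up to 17 calls with DESeq2 and 0 with limma-voom, against 5960 and 4456. The 3 others that also part all 3 replicate pairs gave up to 175 at an unadjusted p and up to 7 with DESeq2. With 10 splits, of which 1 gave as many genes, the share cannot fall under 0.05. Each other split also mixes IP and Input libraries within its groups, so their difference becomes spread within groups. Few calls in those splits were thus fixed in advance, and the contrast lends the calls no support.

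The libraries of replicate 1 deviated together from their group means, with a correlation across genes of 0.574 over 10617 genes with at least 5 CPM, against 0.317 and 0.362 for replicates 2 and 3. After a fit on GC content and transcript length the correlation was 0.581, and without genes on X and Y it was 0.549, which argues against either as the whole cause. Rn45s, a ribosomal RNA, took 11% of the gene reads of IP replicate 1, against 5.8% and 6.02% in IP replicates 2 and 3, but 2.92% in Input replicate 1, against 3.28% and 4.4% in the other Input libraries. This argues against ribosomal RNA taking more reads as the cause in both libraries of replicate 1. Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) had 2 reads in IP replicate 1 and 1 in Input replicate 1, against 1447 to 2880 in each other library. Xist had 20.89, 24.63 and 50.77 CPM by library total in Input replicates 1, 2 and 3, so replicates 2 and 3 held both Y-linked and Xist reads. The Y-linked reads show that replicate 1 did not come from the same set of animals as replicates 2 and 3, which a lane cannot bring about. Whether animals, dissections or lanes caused the shared deviation stays open, since the replicate number is confounded with the lane.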

How the results depend on the processing

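Leaving out clone-accession features together with abundant noncoding RNA was chosen after seeing the data, and the other alternatives were set before. No called gene had the opposite sign among the calls of any alternative, and the sign of 92 called named genes held in all of them. Of these, 67 kept their call in each fit without 1 library and 91 with the replicate block. Rpl9 alone lost its call with the block. Each other named gene whose call ended without 1 library kept it with the block. Without both libraries of replicate 2, 44 lost their call, among them Prph, Glra2, Gabra5, Hrh3, Uqcrq, Atp5d and Peg13. Over all alternatives with 6 libraries, 14 named-gene values lost and 3 gained a call.

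The count of higher genes was 791 at a fold of at least 2 and 2624 with the replicate block, of which 1571 were also called without it. Apart from these and the values given beside results, the block changed no list call at the preset correlation but that of GABA and glycine receptors. The cause was not tested for any change below. Without 1 library or replicate number, higher genes ranged from 83 to 1640 and lower genes from 651 to 2598, lowest without replicate 2.

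Of 15 list calls, 1 held with an estimated correlation, and 0 with both that and the replicate block (oligodendrocyte adjusted p = 0.135). With 6 libraries that test has little to judge spread by, and less with the block. A call lost there does not show that a list did not move. The lists that lost it had medians of 0.737 (thalamic glutamatergic), -2.880 (GABAergic), -1.585 (habenula), 0.462 (pan-neuronal), -3.688 (astrocyte), -3.484 (oligodendrocyte precursor), -4.209 (microglia), -2.481 (endothelial), -3.857 (mural and fibroblast), -3.210 (choroid plexus), -4.233 (erythrocyte), 0.246 (ribosomal proteins), 0.948 (respiratory chain) and -2.698 (long noncoding RNA). By fry, the thalamic (0.737), choroid plexus (-3.210) and ribosomal protein (0.246) lists lost their calls, and the direction was opposite to camera for cortex and hippocampus (-0.168) and channels (-0.040). By fry with the replicate block, only the thalamic, habenula and ribosomal protein lists among the 15 lost their calls (fry adjusted p = 0.104, 0.0919 and 0.158). With the replicate block the camera direction of the cortex and hippocampus list turned from up to down, while its median stayed negative (-0.080).

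GABA and glycine receptors gained a call with RLE (0.303), library totals (0.224), upper-quartile factors (0.200), no filter (0.307) and the replicate block (0.293). They also passed in 3 of 6 fits without 1 library (camera adjusted p up to 0.348 in the 6), and without replicate 1 or replicate 2 (camera adjusted p = 0.00942 and 0.0411). Ribosomal proteins lost theirs with the stricter filter (0.197) and without clone-accession features and abundant noncoding RNA together (0.267).

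Without 1 library or replicate number, list medians ranged from -0.170 to 0.602 for GABA and glycine receptors, -0.658 to 0.590 for cortex and hippocampus, 0.037 to 0.390 for ribosomal proteins, -0.517 to 0.224 for glutamate receptors, -2.276 to 0.410 for hypothalamic genes, 0.009 to 0.676 for immediate-early genes, -0.189 to 0.519 for neuropeptides, -1.506 to 0.071 for striatal genes, -0.244 to 0.147 for channels, -0.132 to 0.357 for monoamine, acetylcholine and opioid receptors, -2.464 to -0.617 for monoaminergic genes and -2.665 to -1.019 for habenula genes, of which the last kept its call in every such fit. Of genes that were not called, Slc17a6 ranged from 0.560 to 2.429, Snap25 from 0.365 to 0.699, Slc17a7 ranged from -0.080 to 0.985, Camk2a from -0.310 to 0.270 and Mef2c from -0.298 to 0.086. Depth limits genes near the floor of 3 reads.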

Other observations

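The tests of equal carry-over for all RNA classes, of carry-over over all 8 lists, of choroid plexus in replicate 3 and of scaling were chosen after their results had been seen. The permutation test of carry-over was set before, but its rank statistic and its minimum of 5 CPM in Input were chosen after list medians had been seen, and the matched lists were set after the rise of the respiratory chain list had been seen. The gene families below were formed from symbols after the data were seen, and 86 were tested. Mitochondrial ribosomal protein genes were higher in IP, with 24 of 47 Mrpl genes and 9 of 29 Mrps genes called higher and 0 lower (camera adjusted p = 2.86e-10 and 1.53e-05, and adjusted p = 0.394 and 0.417 with an estimated correlation). Of 38 Ube genes, many of them ubiquitin-conjugating enzymes, 18 were higher and 0 lower (camera adjusted p = 1.53e-05, and adjusted p = 0.318 with an estimated correlation). Of 15 Sox transcription factor genes, 10 were lower, and of 34 collagen genes, 11 were lower (camera adjusted p = 0.000116 and 0.00832, and adjusted p = 0.359 and 0.318 with an estimated correlation). Neurod6, a gene of cortical excitatory neurons, had 25 CPM in Input replicate 3 and 0.09 and 0.33 CPM in Input replicates 1 and 2. In IP it had 7.89 CPM in replicate 3 and 0.20 and 0.40 CPM in replicates 1 and 2. So IP replicate 3 in part shared the excess of Input replicate 3. Its median deviation from the IP mean was log2 1.24 for GABAergic and 1.13 for choroid plexus genes, but 0.03 for striatal genes.

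Across 14218 protein-coding genes, which are not independent replicates, the log2 fold change correlated with transcript length with r = -0.157, and its median was 0.433 over the 25% of genes with the shortest transcripts and -0.297 over the 25% with the longest. The respiratory chain list may in part follow this trend, since matched lists had a median of 0.756 beside its 0.952. Of 10000 lists matched on length, GC content and expression, 1.13% had a median as high, which argues against the trend as the whole cause. Scaled by library totals only, the list had a median of 0.907 (95% bootstrap interval 0.773 to 0.968) and the other 16444 tested genes one of -0.095 (-0.112 to -0.078). A factor per library moves all genes alike, so it can neither make nor remove the gap between the list and the other genes. This comparison therefore restates the camera result and is no separate test of scaling. The call of the list at the preset correlation was lost with an estimated correlation (adjusted p = 0.173). Higher levels of these transcripts in the tagged cells than in other cells stay open, as untested.

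Non-neuronal transcripts stayed detectable in IP, at a median of 5.1% of the Input level for oligodendrocyte, 5.7% for mural and fibroblast, 6.1% for microglial, 6.8% for astrocyte, 11.1% for oligodendrocyte precursor and 12% for choroid plexus and ependymal genes. A carry-over of input RNA of 1 size for these 6 lists was not excluded (permutation p = 0.0876), though that does not show that they were equal. Endothelial and erythrocyte genes were not in this test, since 2 and 1 of them had at least 5 CPM in Input. With all 131 genes of the 8 lists and no minimum, the endothelial median was 17.9% and the erythrocyte median 5.3% of Input (permutation p = 0.0714). In replicate 3, 6 choroid plexus genes raised in Input had a median log2 ratio of -3.50, within the middle 95% of random lists of other glial and vascular genes (-4.76 to -2.31). These genes were picked by high values in Input replicate 3, the divisor of the ratio, unlike the genes of the random lists. The range is also wide, so this comparison cannot decide on carry-over. Of 3878 features with at least 50 CPM in Input, 16 lay below the lowest list median by more than 2 standard errors. Their median was 1.17% of Input, which goes against 1 carry-over for all RNA. Of these 16, only 3 were protein coding, 3 were lincRNA and 10 had no match in the annotation. Low expression of the tag in other cells was not tested and stays open, and so does whether Input was whole-tissue RNA, on which these percentages depend.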
